A study of Ovis aries with 11 samples.

How the data were processed

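Biopsies from the middle of the biceps femoris were taken at delivery from 11 fetal sheep, 5 control and 6 growth restricted, at 135 days of gestation. Total RNA was isolated with Trizol and column purification, with 1 animal per array, and 300 ng was turned into biotin-labelled cRNA by in vitro transcription from the 3' end, per the labels' protocols. The cRNA was hybridised to Affymetrix Bovine Genome Arrays. Probes designed on cattle sequence can lose signal where sheep sequence differs, and 3' labelling makes probe sets far from the 3' end sensitive to RNA degradation. Both effects act on all arrays, so levels of different probe sets are not compared.

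The deposited values are intensities: linear MAS5 signals made by the authors in Affymetrix Expression Console 1.1, per the submitters' processing notes. The settings of that software, detection calls and scan batches are not given in the sources used here, so no batch could be tested. Each array's mean after trimming 2% at each end is 500.2, so the values were scaled to a common trimmed mean. Such scaling sets equal between arrays only a mean to which bright probe sets contribute most. It leaves the maximum and the median free: array maxima ran from 45354 to 67835 signal units and array medians from 85.7 to 111.7. A group difference in that median moves many dim probe sets in the same direction, and for this reason other scalings were tried.

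Signals under 1 were set to 1 and log2 was taken. The table held 24128 probe sets. The 112 control probe sets were left out of tests, and so were 9578 probe sets whose mean log2 signal over the 11 arrays lay below the 40th percentile (a signal of 51.4), which left 14438. Gene symbols came from the platform's annotation. Of the probe sets that are not controls, 13292 had 1 symbol, 86 several and 10638 none, and no gene was named from a probe set with several. The symbols are cattle gene names and were kept as annotated. A gene was represented by its probe set with the highest mean signal, which gave 7208 genes, and 1608 of these had several tested probe sets. Genome coordinates are not printed, because the annotation used here gives none for the array.

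Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), with Benjamini-Hochberg adjustment over the 14438 probe sets. No covariate was used. Differences are log2 IUGR minus control. Gene lists for the tissue and the treatment, and marker lists of other cell types, were tested with camera at a preset correlation of 0.01 on the representative probe sets, with at least 5 measured members, and adjusted over 34 lists. The same test with an estimated correlation was run beside it. The per-array list score is the mean log2 signal of the members minus the mean of all genes on that array. List scores and array quality measures were compared with two-sided exact permutation tests over all 462 splits of the arrays into 5 and 6. Quality measures were the array median, the share of probe sets below the filter level, the 3' minus 5' signal of the actin and GAPDH control sets, and the mean of 18 bacterial hybridization control sets.

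The genes named were fixed by a rule: in each direction up to 12 past the threshold with the largest log2 difference and a level at or above the median probe set, filled up to 6 by the lowest p where fewer passed; in each list up to 4 members past the threshold, or else the 2 with the lowest p; and a set of growth, muscle and metabolic genes named always where tested. Groups, tests, lists, this rule and the following alternatives were fixed before the data were examined: other filters, quantile normalization, median centring, an offset of 16, other variance models, array weights, an unmoderated test, the replicate number as a block, an adjusted p of 0.1, the mean of a gene's probe sets, other list tests, and leaving out each array in turn. Scaling to the hybridization controls, their group difference as a quality measure, *XIST* as a covariate and the exact test of list scores as an alternative were added after seeing the data.

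The test was checked on simulated data for 14438 probe sets with the spread of these arrays and 50 changed probe sets at each size. It recovered 12% of changes of 0.5 on the log2 scale, 60% of changes of 1, 92% of changes of 2 and 100% of changes of 3, with 5 false calls. With no change simulated it called 2, and 710 had an unadjusted p under 0.05. A simulation with an effect shared by a list's genes within each animal (SD 0.5) and no group effect called the G2/M list in 20% of 50 runs at the preset correlation and in 2% with the estimated one. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.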

Results

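Gene expression was measured in the biceps femoris, a mixed hindlimb muscle, of 11 fetal sheep at 135 days (90% of gestation). Of these, 5 fetuses grew normally (control) and 6 had intrauterine growth restriction (IUGR). Growth restriction followed from placental insufficiency, produced by keeping the pregnant ewe in a chamber cycled between 40 °C and 35 °C every 12 h at 40% humidity for 80 days. Control ewes were kept at ambient temperature and fed the same amount. Each fetus gave 1 array, so the spread within a group is the spread between animals. Sheep RNA was hybridised to bovine probes, and a probe set reads a sheep transcript only as far as the bovine sequence matches it. Of 24128 probe sets, 14438 were bright enough to be tested, and these named 7208 genes. The arrays correlated with each other at r = 0.915 to 0.931 across probe sets, and no pair of arrays held identical values. Array signals carry no read depth, and the number of arrays limits the precision.

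The comparison asked which transcripts of fetal muscle differ when growth is restricted. Among the gene lists, the largest score difference was in genes of mitosis. All 20 measured members of the G2/M and mitosis list were lower in IUGR muscle, with a median log2 difference of -1.13. Endothelial marker genes were lower as well, all 13 of 13 in the authors' scaling, with a median of -0.46. Proteasome subunits were higher as a group, by a score difference of 0.19 in the authors' scaling and 0.08 after quantile normalization. Glucocorticoid-responsive genes were also higher as a group, the call ending without IUGR replicate 5 (score difference 0.26). Fast fibre genes were lower as a group in the authors' scaling, while 10 of 12 were higher after hybridization control scaling, and without IUGR replicate 5 their score difference was 0.02. These 5 of 34 gene lists passed limma's camera test at a preset correlation between genes. None of them passed when the correlation was estimated from the arrays. No individual gene passed the threshold.

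At the level of single probe sets, limma called 0 of 14438 past an adjusted p of 0.05, and the smallest adjusted p was 0.119. The unmoderated test of each probe set also called 0. At an unadjusted p under 0.05 there were 1720 probe sets in limma's test, against 721.9 expected by chance, and 1655 in the unmoderated test. Of the 1720, 476 were higher and 1244 lower in IUGR, so 72.3% were lower. That share moved with the scaling of the arrays. After quantile normalization 729 were higher and 722 lower, after median centring 1154 higher and 602 lower, and after scaling to the bacterial hybridization controls 2180 higher and 175 lower. The median log2 difference over all tested probe sets was -0.09 in the authors' scaling, 0.03 after median centring and 0.19 after hybridization control scaling. The sign changed after hybridization control scaling for 16 of the 97 genes named here, none of them past the threshold. Gene values are given in the authors' scaling, and list scores are taken relative to all genes of the same array.

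The genes with the lowest p, none past the threshold, had varied functions. *LOXL1*, a lysyl oxidase relative that cross-links elastin, had a log2 signal of 9.58 ± 0.11 (SD, n = 5) in control and 8.62 ± 0.31 (SD, n = 6) in IUGR muscle. Its log2 difference was -0.95 (SE 0.16, limma adjusted p = 0.119), or 1.94-fold lower, and all 6 IUGR arrays lay below the control mean. Without IUGR replicate 4 its adjusted p was 0.0434. *UBE2C*, the ubiquitin-conjugating enzyme of the anaphase-promoting complex, differed by -1.35 (SE 0.24, adjusted p = 0.127), or 2.54-fold. *TPPP3*, a tubulin-binding protein, differed by -1.39 (SE 0.26), and *MAPK8IP1*, a scaffold of the JNK kinase cascade, by -1.06 (SE 0.20). The kinetochore gene *MIS12* and the surface glycoprotein gene *CD99* each differed by -0.80 (SE 0.17). In the other direction, *LIMS2*, an adaptor of integrin-linked kinase, was 1.96-fold higher (log2 difference 0.97, SE 0.20, adjusted p = 0.220), and *TNRC6B*, which acts in microRNA silencing, was 1.46-fold higher (0.55, SE 0.11, adjusted p = 0.220). The autophagosome gene *MAP1LC3B* was at 13.75 ± 0.23 in IUGR against 13.03 ± 0.37 in control muscle. *TEAD3*, a transcription factor of the Hippo pathway, differed by 0.74 (SE 0.18), *TFIP11*, which acts in spliceosome disassembly, by 0.60 (SE 0.15), and the nuclear import receptor gene *IPO7* by 0.45 (SE 0.11).

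Cell division genes were lower together. The per-array score of the G2/M and mitosis list (mean log2 signal of its members minus the mean of all genes) was -1.06 ± 0.52 (SD, n = 5) in control and -2.01 ± 0.47 (SD, n = 6) in IUGR muscle, a difference of -0.95 (SE 0.30). All 6 IUGR arrays lay below the control mean, and 3 lay below every control array. Over the list alone, 15 of 20 members passed adjusted p 0.05, all lower, while over all genes tested 0 did. *NUSAP1*, a spindle microtubule protein, was 3.18-fold lower (log2 difference -1.67, SE 0.36, list-alone adjusted p = 0.00397). *UBE2C* had an adjusted p of 0.00123 over the list alone. *CDK1*, the kinase that drives entry into mitosis, was at 7.19 ± 0.63 in control and 6.15 ± 0.49 in IUGR muscle, 2.05-fold lower. Camera gave an adjusted p of 2.00e-11 for the list at the preset correlation, and an adjusted p of 0.604 with an estimated correlation. The exact permutation test of the list score gave p = 0.0173 (adjusted p = 0.221 over 34 lists). All 20 members were also lower after quantile normalization and median centring, and 18 of 20 after hybridization control scaling. Endothelial markers were lower in the same arrays, by -0.36 in score.

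**Figure D1:**
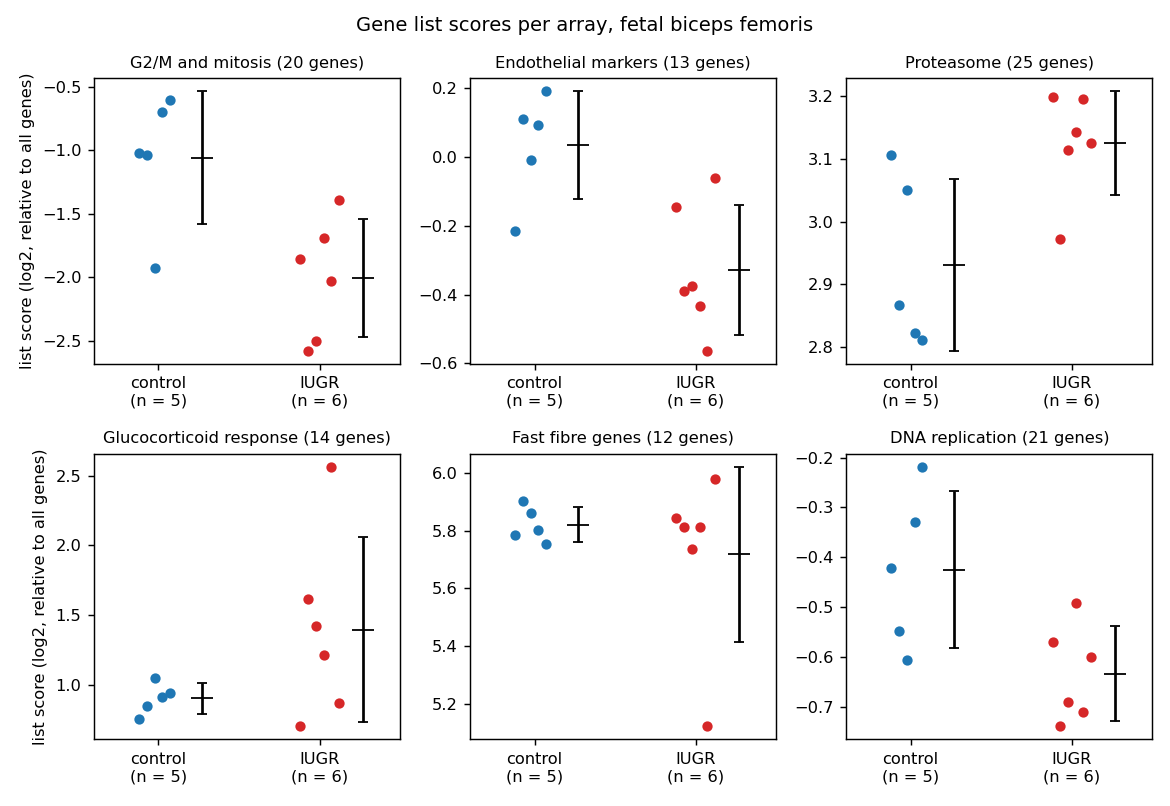
Each panel plots a gene list's score per array (log2, mean of the list's members minus the mean of all genes of that array) for control (blue, n = 5) and IUGR (red, n = 6) fetuses, with the group mean and SD as a bar beside the points; vertical scales differ between panels. G2/M scores average -1.06 in control and -2.01 in IUGR muscle, and in the glucocorticoid and fast fibre panels IUGR replicate 5 lies far from the other arrays, at 2.56 and 5.12.

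The lists of genes acting before mitosis did not pass. The DNA replication list missed the threshold (score difference -0.21, SE 0.08, camera adjusted p = 0.0705), and none of its 21 members passed over the list alone. It passed as lower after quantile normalization (adjusted p = 0.0495) and hybridization control scaling (adjusted p = 0.0179), with the mean of probe sets per gene, and without control replicate 2, control replicate 3 or IUGR replicate 4. These calls are at the preset correlation; with the estimated one (0.0716) the adjusted p was 0.604 in the authors' scaling. In that list, *PCNA*, the sliding clamp of replication, had a log2 difference of -0.42 (SE 0.15) and *TYMS*, thymidylate synthase, one of -1.10 (SE 0.44). The IUGR mean of *TYMS*, 5.38, lay below the filter level of 5.68, so the size of its difference is uncertain. The G1/S and cyclin list did not pass (camera adjusted p = 0.939). Within it, *CCNE2*, cyclin E2, was lower (log2 difference -1.13, SE 0.33, list-alone adjusted p = 0.0417), *MYC* differed by 0.66 (SE 0.28), and *CCND1*, cyclin D1, by 0.00 (SE 0.32). Among 7 cell cycle inhibitors, 1 passed over the list alone in each direction. *CDKN1A*, the p53 target p21, was at 9.76 ± 0.56 in control and 11.26 ± 1.14 in IUGR muscle (log2 difference 1.51, SE 0.45, list-alone adjusted p = 0.0168). *CDKN2C*, an inhibitor of CDK4 and CDK6, differed by -1.05 (SE 0.30, list-alone adjusted p = 0.0168). The inhibitor list as a whole did not pass (camera adjusted p = 0.610).

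Endothelial markers were lower in IUGR muscle. The endothelial score was 0.03 ± 0.16 in control and -0.33 ± 0.19 in IUGR muscle, a difference of -0.36 (SE 0.10), with 6 of 6 IUGR arrays below the control mean. *TIE1*, an endothelial receptor tyrosine kinase, was 1.59-fold lower (log2 difference -0.67, SE 0.15, list-alone adjusted p = 0.00795), the only 1 of 13 members to pass over the list alone. The tight junction gene *CLDN5* differed by -0.82 (SE 0.31). Camera gave an adjusted p of 0.00278, and an adjusted p of 0.604 with an estimated correlation; the exact permutation p of the score was 0.0152 (adjusted p = 0.221). All 13 members were lower in the authors' scaling, 12 after quantile normalization, 10 after median centring and 8 after hybridization control scaling. The G2/M score was lower in the same arrays.

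**Figure D2:**
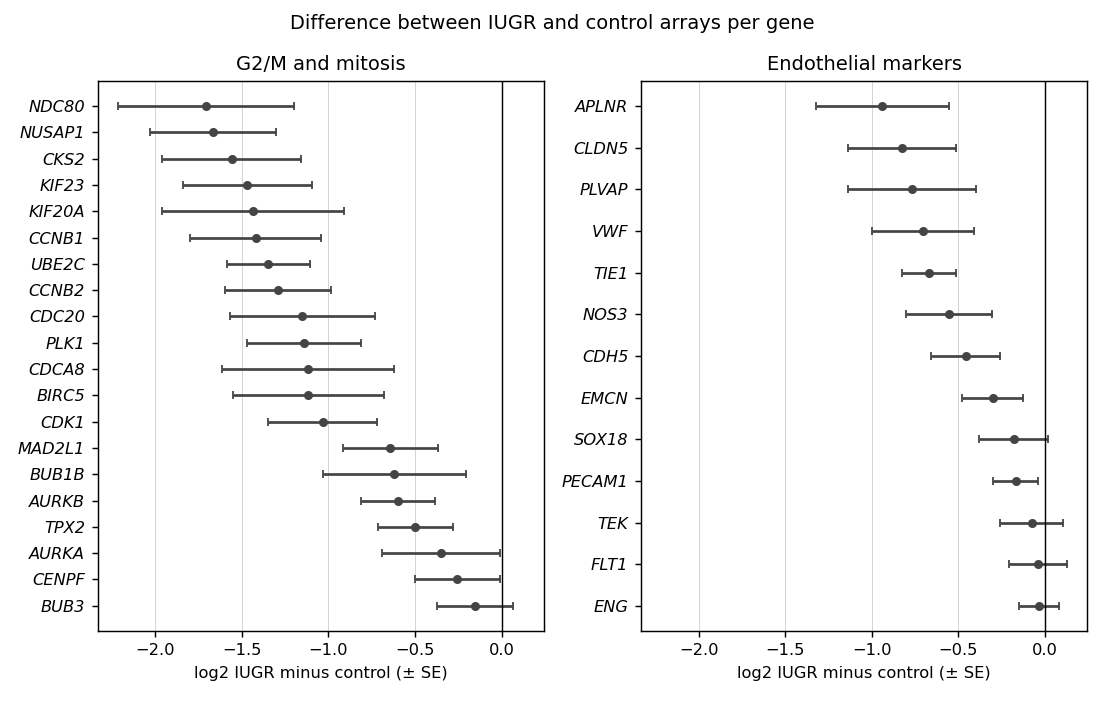
Points show the log2 difference between IUGR (n = 6) and control (n = 5) arrays for each measured gene of the G2/M and mitosis list (left) and the endothelial marker list (right), with limma's SE as bars and a line at 0; values are in the authors' scaling. All points lie below 0, from -1.71 for *NDC80* to -0.15 for *BUB3* on the left and from -0.94 for *APLNR* to -0.04 for *ENG* on the right.

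No list of other cell type markers passed as reported. Fibroblast markers did under 8 alternatives, and tendon and cartilage markers did without control replicate 2, at the preset correlation. The fibroblast and extracellular matrix list had a score difference of -0.12 (camera adjusted p = 0.0761). Relative to other genes it passed as lower after quantile normalization (adjusted p = 0.0244) and hybridization control scaling (adjusted p = 0.0378). It also passed with the stricter filter, with the mean of probe sets per gene, and without control replicate 1, control replicate 3, IUGR replicate 2 or IUGR replicate 5. These calls are at the preset correlation; with the estimated one (0.0957) the adjusted p was 0.604 in the authors' scaling, and the exact permutation p was 0.238. In it, 2 of 26 members passed over the list alone, both lower: *POSTN*, the matrix protein periostin, at -1.26 (SE 0.30) and *SPARC*, a collagen-binding matrix protein, at -0.70 (SE 0.20). Basement membrane genes (camera adjusted p = 0.939) included *COL4A1* at -0.26 (SE 0.10) and *LAMC1* at 0.23 (SE 0.11), with 3 of 4 other *LAMC1* probe sets of opposite sign. Pericyte and smooth muscle markers (camera adjusted p = 0.977) included *SMTN* at -0.37 (SE 0.14) and *MCAM* at -0.22 (SE 0.20). Leukocyte markers (camera adjusted p = 0.939) included *CSF1R* at 0.45 (SE 0.18) and *CD3E* at -0.42 (SE 0.22). Adipocyte markers (camera adjusted p = 0.939) included *CIDEC* at -0.67 (SE 0.37) and *FASN* at -0.47 (SE 0.31). The IUGR mean of *CIDEC*, 5.44, lay below the filter level of 5.68. Erythroid markers (camera adjusted p = 0.939) included *CA2* at -0.53 (SE 0.23) and the haemoglobin chaperone gene *AHSP* at 0.99 (SE 0.43). Tendon and cartilage markers (camera adjusted p = 0.465) included *MATN1* at -0.33 (SE 0.18) and *COL11A1* at 0.62 (SE 0.39), with 1 of 2 other *COL11A1* probe sets of opposite sign. Only 3 nerve and Schwann cell markers were measured, too few for the list test, among them *S100B* at -0.50 (SE 0.20) and *NGFR* at -0.40 (SE 0.33).

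Of the protein breakdown lists, the proteasome passed. Its score was 2.93 ± 0.14 in control and 3.12 ± 0.08 in IUGR muscle, a difference of 0.19 (SE 0.07), with 6 of 6 IUGR arrays above the control mean. The regulatory subunit genes *PSMD11* and *PSMD14* had log2 differences of 0.34 (SE 0.11) and 0.23 (SE 0.09), and no member passed over the list alone. Of 25 members, 20 were higher in the authors' scaling and after quantile normalization, and 25 after median centring and after hybridization control scaling. After quantile normalization the score difference was 0.08 (camera adjusted p = 0.0460). Its size thus depended on the scaling, and array scale as a source of part of it was not tested. Camera gave an adjusted p of 5.03e-05, and an adjusted p of 0.604 with an estimated correlation; the exact permutation p of the score was 0.0216 (adjusted p = 0.221). The proteolysis and autophagy list did not pass (score difference 0.17, SE 0.12, camera adjusted p = 0.115). In that list *MAP1LC3B* was higher by 0.72 (SE 0.16, list-alone adjusted p = 0.00809), and *ATG5* differed by -0.24 (SE 0.13). *FBXO32*, the muscle ubiquitin ligase atrogin-1, differed by -0.07 (SE 0.43), with IUGR replicate 5 at 10.86 and the other 5 IUGR arrays between 7.82 and 8.57, all below the control mean of 8.71. Without IUGR replicate 5 its difference was -0.52.

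Glucocorticoid-responsive genes were higher as a group, with a wide spread among IUGR animals. The score was 0.90 ± 0.11 in control and 1.40 ± 0.66 in IUGR muscle, a difference of 0.49 (SE 0.28), and 4 of 6 IUGR arrays lay above the control mean. *CEBPD*, a stress-induced transcription factor, was at 9.41 ± 0.49 in control and 11.13 ± 1.38 in IUGR muscle (log2 difference 1.72, SE 0.52). *PDK4*, the kinase that inactivates pyruvate dehydrogenase, was at 8.42 ± 0.23 and 10.14 ± 1.68 (1.71, SE 0.61). Neither passed over the list alone, and no other of the 14 members did. In the authors' scaling and after quantile normalization 11 members were higher, 12 after median centring and 13 after hybridization control scaling. The 3 lower members in the authors' scaling were the receptor gene *NR3C1* at -0.35 (SE 0.14), *DUSP1* at -0.25 (SE 0.25) and *SGK1* at -0.11 (SE 0.15). *FKBP5*, *TSC22D3*, *PER1* and *KLF9* were not among the members tested. Camera gave an adjusted p of 0.0244, and an adjusted p of 0.604 with an estimated correlation; the exact permutation p of the score was 0.115. The call ended without IUGR replicate 5 (score difference 0.26, adjusted p = 0.221), without control replicate 2 (adjusted p = 0.0501) and after quantile normalization (adjusted p = 0.0622), median centring (adjusted p = 0.0867) or hybridization control scaling (adjusted p = 0.103). It also ended with the stricter filter (adjusted p = 0.0640) and with array weights (adjusted p = 0.0753).

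**Figure D3:**
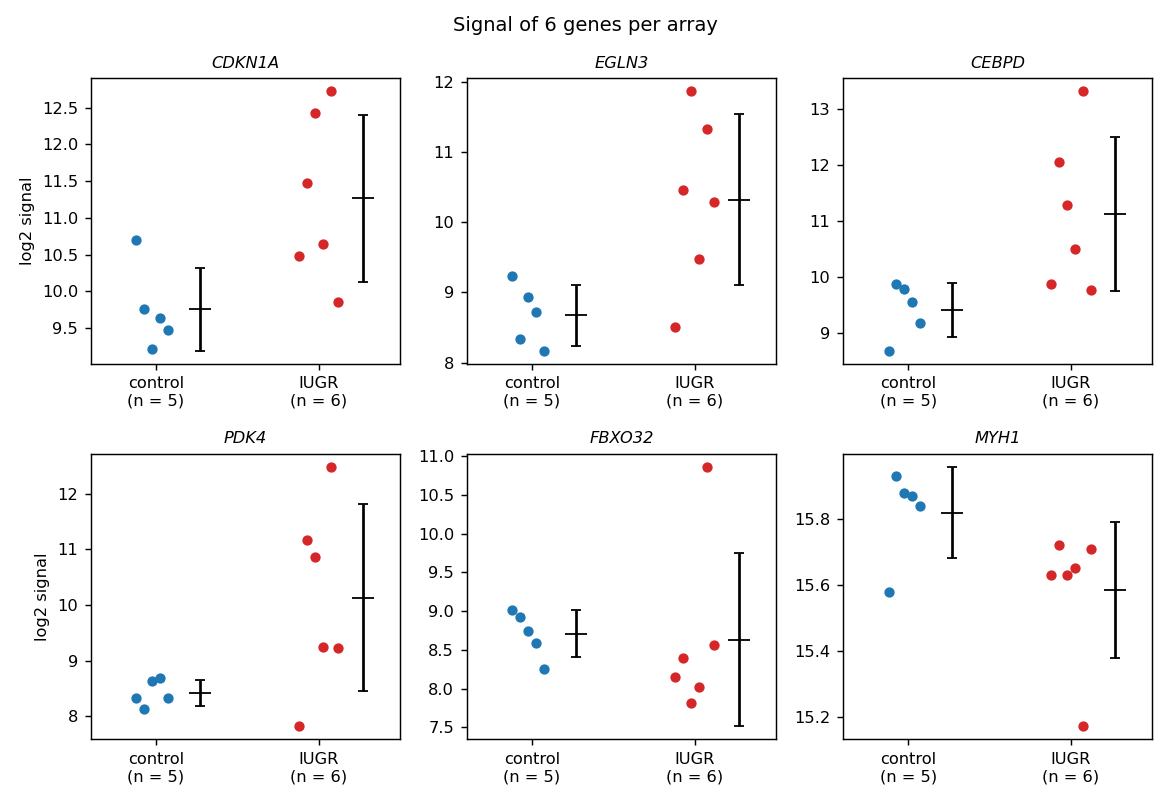
Log2 signal per array of 6 genes in control (blue, n = 5) and IUGR (red, n = 6) fetuses, with the group mean and SD as a bar beside the points; vertical scales differ between panels. IUGR replicate 5 is the highest array for *CDKN1A* (12.72), *CEBPD* (13.32), *PDK4* (12.48) and *FBXO32* (10.86), and the lowest for *MYH1* (15.17).

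Other stress lists did not pass. The hypoxia list had a score difference of 0.32 (SE 0.17, camera adjusted p = 0.0705), with 3 members higher and 1 lower over the list alone. *EGLN3*, a hypoxia-induced prolyl hydroxylase, was 3.12-fold higher (log2 difference 1.64, SE 0.47, list-alone adjusted p = 0.0445), and *EGLN1* differed by 0.35 (SE 0.11), with 1 of its 2 other probe sets of opposite sign. The glucose transporter gene *SLC2A1* differed by 0.47 (SE 0.25). In the integrated stress and unfolded protein response list (camera adjusted p = 0.697), *CALR* differed by -0.37 (SE 0.13) and *ATF4* by 0.38 (SE 0.14). Heat shock proteins, of interest because the ewes were kept in heat, did not pass as a list (camera adjusted p = 0.691). Among them *CRYAB* differed by 0.61 (SE 0.23) and *HSF1* by 0.20 (SE 0.10), with its other probe set of opposite sign. Inflammation genes (camera adjusted p = 0.115) included *IL6R* at 0.65 (SE 0.24) and *NFKBIA* at 0.45 (SE 0.25; 0.23 without IUGR replicate 2), with 3 of 6 IUGR arrays below the control mean for *NFKBIA*. This list passed after quantile normalization (adjusted p = 0.0460, 12 of 14 members higher) and without control replicate 2, at the preset correlation. With the estimated one (0.147) camera's adjusted p was 0.604 in the authors' scaling, and the exact permutation p of the score was 0.110. Interferon response genes (camera adjusted p = 0.272) included *MX1* at -0.56 (SE 0.26) and *RSAD2* at -0.38 (SE 0.24).

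Of the contractile lists, the fast fibre genes passed. The signals of *MYH1*, of many other fast fibre genes and of the slow fibre gene *MYH7* lay near the top of each array's range, where differences can be compressed. In control muscle *TNNC2*, *MYL1* and *CKM* were at 15.84, 15.75 and 15.65. The highest signal of an array was lowest in IUGR replicate 5 (45354 signal units) and control replicate 1 (50232). *MYH1* was also lowest in these arrays. Since *MYH1* itself lies near the top of the range, the maximum is no separate measure of array scale. It cannot decide whether scale lowered these values. The fast fibre list had a score of 5.82 ± 0.06 in control and 5.72 ± 0.30 in IUGR muscle (difference -0.10, SE 0.13, exact permutation p = 0.706), with 4 of 6 IUGR arrays below the control mean. All 12 members were lower in the authors' scaling and after quantile normalization, 9 after median centring and 2 after hybridization control scaling. *MYH1*, the heavy chain of fast IIX fibres, differed by -0.24 (SE 0.10), and its 7 other probe sets by -0.92 to -0.04. *TPM1* differed by -0.32 (SE 0.14), with its other probe set of opposite sign. No member passed over the list alone. Camera gave an adjusted p of 0.0307, and an adjusted p of 0.767 with an estimated correlation. Without IUGR replicate 5 the score difference was 0.02 (camera adjusted p = 0.403), and the call also ended without control replicate 2, 3 or 4 (adjusted p = 0.0956, 0.0536 and 0.0521). It ended as well after median centring (adjusted p = 0.144) and hybridization control scaling (adjusted p = 0.962), and in further alternatives given below. Slow fibre genes did not pass as a list (camera adjusted p = 0.833); *MYL3* differed by 1.37 (SE 0.46; 0.89 without control replicate 2, which lay lowest at 9.37), *MYL2* by -0.20 (SE 0.10) and *MYH7*, the slow heavy chain, by -0.04 (SE 0.11), with its other probe set of opposite sign. In the embryonic and neonatal sarcomere list (camera adjusted p = 0.641), *CHRNG*, the fetal acetylcholine receptor subunit, was lower (-0.72, SE 0.23, list-alone adjusted p = 0.0430) and *TNNT2* differed by 0.96 (SE 0.41). The developmental heavy chains *MYH8* and *MYH3* differed by -0.37 (SE 0.16) and -0.20 (SE 0.31). Myogenic regulators (camera adjusted p = 0.207) included *MEF2C* at -0.50 (SE 0.16) and *MYF6* at -0.44 (SE 0.16). *MYOD1* differed by 0.21 (SE 0.29), *MYOG* by -0.23 (SE 0.27) and *MSTN*, the growth inhibitor myostatin, by -0.50 (SE 0.25).

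Growth factor, translation and transport lists gave no call. In the IGF and insulin list (camera adjusted p = 0.115), *TBC1D4*, which controls movement of the glucose transporter GLUT4, differed by -0.43 (SE 0.13) and *GRB10*, an inhibitory receptor adaptor, by -0.51 (SE 0.18). *IGF1* differed by -0.34 (SE 0.17), *IGF2* by -0.17 (SE 0.09), *IGF1R* by 0.07 (SE 0.26) and *SLC2A4*, which encodes GLUT4, by 0.33 (SE 0.30). Translation initiation genes (camera adjusted p = 0.284) included *EIF4G1* at 0.35 (SE 0.13) and *EIF4A1* at 0.24 (SE 0.13). Cytosolic ribosomal proteins (camera adjusted p = 0.630) included *RPL11* at -0.19 (SE 0.11) and *RPL22* at -0.14 (SE 0.09). This list passed as higher after hybridization control scaling (adjusted p = 0.00418), and so did oxidative phosphorylation (adjusted p = 0.00207). Both calls are at the preset correlation of 0.01, where the estimates for these lists were 0.649 and 0.620; with the estimated correlation, in the authors' scaling, the adjusted p was 0.985 for each. Amino acid transport genes (camera adjusted p = 0.770) included *SLC7A7* at -0.43 (SE 0.20) and *SLC7A5* at -0.81 (SE 0.40). Adrenergic signalling genes (camera adjusted p = 0.939) included *GNAS* at -0.21 (SE 0.10), with 3 of 4 other probe sets of opposite sign, and *NR4A1* at 0.33 (SE 0.16).

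No list of energy metabolism passed as reported. Fatty acid oxidation passed without control replicate 3 and without IUGR replicate 5, at the preset correlation. With the estimated one (0.192) camera's adjusted p was 0.767 in the authors' scaling. Oxidative phosphorylation (48 genes measured, camera adjusted p = 0.939) included *COX7C* at -0.24 (SE 0.09) and *ATP5MC3* at -0.19 (SE 0.10). The pyruvate dehydrogenase and TCA cycle list (camera adjusted p = 0.939) held *PDK4* and *PDP1*, the phosphatase that activates pyruvate dehydrogenase, which differed by -0.44 (SE 0.15). Fatty acid oxidation (camera adjusted p = 0.115) included the uncoupling protein gene *UCP3* at -1.12 (SE 0.40) and *ETFB* at 0.36 (SE 0.17). Glycolysis and glycogen genes (camera adjusted p = 0.939) included *LDHB* at -0.25 (SE 0.12) and *UGP2* at 0.18 (SE 0.09). Amino acid catabolism (camera adjusted p = 0.939) included *GPT* at -0.59 (SE 0.26) and *BCAT2* at -0.43 (SE 0.21). Thyroid hormone and circadian lists had 4 measured members each, too few for the list test. Of the thyroid hormone genes, *ME1*, malic enzyme, at 0.62 (SE 0.25), *THRA*, the hormone's receptor, at 0.29 (SE 0.12), and *UCP3* each had an adjusted p of 0.0379 over the list alone; *THRA* was chosen after its value was seen. The clock genes *BHLHE40* and *NR1D1* differed by 0.16 (SE 0.15) and 0.20 (SE 0.23), the other *BHLHE40* probe set having the opposite sign. *XIST*, the sole sex-linked transcript measured, was high (10.22 to 10.64) in replicates 1, 3 and 5 of each group. It was low (3.55 to 5.75) in the other arrays, which reads as both sexes in each group. Fetal sex is not in the labels. The log2 difference of *XIST* was -0.68 (SE 1.45). *INSR*, *IRS1*, *PAX7*, *MYF5*, *MYH2*, *ADRB2* and *TRIM63* were not analysed here.

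Array measures differed between the groups in scale. The median log2 signal of all probe sets was 6.68 ± 0.12 in control and 6.49 ± 0.06 in IUGR arrays (exact permutation p = 0.00866, adjusted p = 0.0216 over 5 measures). Probe sets below the filter level made up 35.9% ± 2.1 and 39.1% ± 0.9 (exact permutation p = 0.00866). The hybridization controls, bacterial transcripts added to every sample, averaged 12.55 ± 0.21 and 12.27 ± 0.16 (exact permutation p = 0.0411, adjusted p = 0.0685). Signs of RNA degradation did not differ past the threshold. The 3' minus 5' log2 signal of actin was 0.67 ± 0.12 in control and 0.76 ± 0.14 in IUGR arrays (exact permutation p = 0.318), and that of *GAPDH* was 0.62 ± 0.11 and 0.66 ± 0.09 (exact permutation p = 0.487).

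In 10 lists that did not pass, the median, the mean or the score difference differed in sign from camera's direction. These were the slow fibre, ribosomal protein, amino acid catabolism, glycolysis, pyruvate dehydrogenase, oxidative phosphorylation, heat shock, basement membrane, pericyte and erythroid lists. For the slow fibre genes the median log2 difference was -0.10 and the score difference 0.15. For the erythroid markers the median was -0.14 and the score difference 0.07.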

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

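Both tests of IUGR replicate 5 were chosen after its values were seen. Of 214 groups of arrays checked (each named gene, called list and quality measure in each group), 15 held an array far from the others of its group, judged by its gap to the nearest array as a share of the group's range. About 1 in 20 such groups is expected to do so by chance.

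IUGR replicate 5 lay apart in 4 of them. Its *FBXO32* log2 signal was 10.86, against 7.82 to 8.57 in the other IUGR arrays (gap share 0.752). *MYH1* was at 15.17 against 15.63 to 15.72 (0.834), *CD3E* at 6.51 against 7.36 to 7.85 (0.639), and the fast fibre score at 5.12 against 5.74 to 5.98 (0.717). Control replicate 1 lay apart in 5 genes. These were *MYH1* at 15.58 against 15.84 to 15.93 (0.754), *GRB10* at 7.46 against 7.99 to 8.11 (0.813), *ATG5* at 8.86 against 9.19 to 9.25 (0.836), *UCP3* at 8.37 against 7.58 to 7.81 (0.713) and *CLDN5* at 6.41 against 7.57 to 7.91 (0.773). Control replicate 1 and IUGR replicate 5 also had the lowest maximum signals of the arrays. *MYH1* itself lies near the top of the range, so these maxima cannot decide whether its values reflect array scale, which was not tested. Control replicate 4 lay apart in *RSAD2*, at 8.29 against 7.11 to 7.40 (0.756), and *MYH3*, at 14.15 against 13.50 to 13.58 (0.874). IUGR replicate 6 lay apart in *IPO7*, at 11.72 against 11.39 to 11.50 (0.649), and *IGF1*, at 7.36 against 7.97 to 8.12 (0.802). IUGR replicate 1 had *SLC7A5* at 4.24 against 5.87 to 6.78 (0.643), and IUGR replicate 2 a proteasome score of 2.97 against 3.11 to 3.20 (0.626).

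The array of IUGR replicate 5 was the highest or lowest of the 11 arrays in 15 of 34 list scores, where 6.18 would be expected for an array by chance. Its raised genes included *ADM*, *MT1A*, *PFKFB3* and *FBXO32*, and the fast fibre gene *ACTN3* was at 10.50 against 13.20 to 14.30 in the other arrays; these genes were chosen after their values were seen. RNA degradation is argued against, since its mean 3' minus 5' control signal of 0.688 lay within the 0.574 to 0.799 of the other arrays. Marker scores cannot decide on tissue of another kind in the biopsy. Of these, 0 of 8 lay above the other 10 arrays and 3 lay below, but an ordinary array may also top none. The marker lists also hold none for another muscle or fibre region. Part of the pattern was shared with other IUGR arrays, most clearly with IUGR replicates 2 and 3. *PDK4* was at 11.17 and 10.87 there, *CEBPD* at 12.05 and 11.29, and *CDKN1A* at 11.47 and 12.42, each above every control array. Also above every control array were *PDK4* in IUGR replicates 4 and 6 (9.25 and 9.23) and *CEBPD* in replicates 1 and 4 (9.88 and 10.50). The remaining values of these genes in replicates 1, 4 and 6 were not. *FBXO32* was not raised in replicates 2 and 3, at 8.39 and 7.82. An acute stress of this fetus may account for the rest of the pattern and was not tested, and neither was handling of this sample.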

How the results depend on the processing

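The *XIST* covariate, hybridization control scaling, the hybridization control measure and the exact permutation of list scores were chosen after seeing the data. Counts of probe sets and of genes past the threshold were 0 under every alternative except some that left out an array. There the probe set count ran from 0 to 4 (4 without control replicate 3, 2 without IUGR replicate 4) and the gene count from 0 to 2. *UBE2C* and *NUSAP1* had an adjusted p of 0.0499 without control replicate 3, and *LOXL1* one of 0.0434 without IUGR replicate 4. The cause was not tested.

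The count of lists past the threshold, 5 as reported, was 3 after median centring, 3 with array weights and 8 at an adjusted p of 0.1. It was 0 with an estimated correlation, 0 with fry and 0 with the exact permutation of list scores. The first 2 of these take the correlation of a list's genes between animals from the arrays, which the preset value of 0.01 does not: the estimate was 0.512 for the G2/M list. With 462 splits the smallest exact p, adjusted over 34 lists, is 0.0736 for a list that is alone in reaching it, so the last test could pass only several lists together. Leaving out an array gave 4 to 9 lists, with 9 without control replicate 1 and 8 without IUGR replicate 4. The cause of the other moves was not tested. All other alternatives with a value gave 4 to 7 lists; the robust trend and the unmoderated test do not enter the list test, which kept its 5 lists. Of the lists not past the threshold as reported, fibroblast markers passed in 8 alternatives at the same threshold, DNA replication in 6 and hypoxia in 4. The IGF and insulin, ribosomal protein, fatty acid oxidation and inflammation lists passed in 2 each. Interferon response, tendon and cartilage markers and oxidative phosphorylation passed in 1 each, the interferon list without IUGR replicate 4.

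The G2/M, endothelial and proteasome lists stayed past the threshold in every alternative except those 3, the proteasome score difference being 0.08 after quantile normalization and 0.19 as reported. The fast fibre score difference ran from -0.156 to 0.0163 when an array was left out, and the value above 0 was that without IUGR replicate 5; its call was lost in 13 alternatives in all, with adjusted p from 0.0519 with no filter to 0.962 after hybridization control scaling, and 0.118 with no intensity trend, 0.0997 with array weights, 0.144 after median centring and 0.178 with the mean of probe sets per gene. The glucocorticoid list lost its call in 10 alternatives in all, with adjusted p from 0.0501 to 0.685. Of 2312 values of named genes under the alternatives, 43 changed sign, with no call in either setting, 16 of them after hybridization control scaling. Leaving out an array moved some larger differences over 1.5 times: *CD3E*, *GPT* and *SLC2A1* to -0.23, -0.36 and 0.29 without IUGR replicate 5, *CIDEC*, *FASN* and *MYL3* to -0.43, -0.24 and 0.89 without control replicate 2 (*COL11A1*, at 0.62 as reported, was larger there), *NFKBIA* to 0.23 without IUGR replicate 2, and *SLC7A5* to -0.46 without IUGR replicate 1; *XIST* moved in every such set.

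The group difference in hybridization controls was -0.35 to -0.21 with an array left out, and missed an exact permutation p of 0.05 in 9 of these 11 sets. The cause was not tested. The other 4 quality measures kept their side of the threshold in every such set.

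With the replicate number as a block (numbers 1 to 5), limma called 0 probe sets and 0 genes, and camera 5 lists. Deviations of arrays with the same number correlated at -0.054 to 0.063, and 2 of 5 control arrays correlated best with the IUGR array of their own number. These correlations showed no pairing by number. *XIST* did follow the number. It was high in replicates 1, 3 and 5 of both groups. In replicates 2 and 4 it was low, at 4.94 and 5.75 in control and 3.55 and 5.29 in IUGR arrays. Whether the numbers pair animals stays open. Detection calls were not used here, so the filter level is the only limit on dim transcripts.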

Other observations

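The tests against a loss of non-muscle cells and the count of splits at an unadjusted p were chosen after the results were seen; the 3 gene lists described next were chosen after the main results, and their outcomes were predicted before they were computed. Mitotic genes outside the G2/M list were lower in IUGR muscle too. Of 19 measured, 18 were lower and 10 passed adjusted over the list alone, with a median log2 difference of -0.69. *ECT2*, which positions the cleavage furrow, differed by -1.07 (SE 0.28), *HMMR*, a spindle protein, by -1.01 (SE 0.28) and *STMN1*, which destabilises microtubules, by -0.65 (SE 0.18). Camera gave an adjusted p of 2.14e-08 over the 3 added lists and an adjusted p of 0.0484 with an estimated correlation, and the exact permutation p of the score was 0.00433. These genes are transcribed together with those of the G2/M list in the same animals, so they are no independent sample.

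Imprinted growth genes had a median of -0.17 over 15 measured genes, with 0 past the threshold over the list alone; *GRB10* and *NNAT* differed by -0.51 (SE 0.18) and -0.79 (SE 0.29). The prediction that they move together stays undecided, since camera gave an adjusted p of 0.0310 and an adjusted p of 0.413 with an estimated correlation (exact permutation p = 0.258). Collagen processing enzymes other than *LOXL1* did not pass (16 measured, camera adjusted p = 0.435). The bound set for that test was wrong, since a p that misses the threshold excludes nothing, and the values go both ways. In the authors' scaling 10 of the 16 were lower (median -0.20), while the score relative to all genes differed by 0.01 (exact permutation p = 0.931), so a lower level of these enzymes beside low *LOXL1* stays undecided.

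The lower G2/M score of IUGR muscle was weighed against technical causes. A difference in array scale as the whole cause is argued against, because the score difference was -0.89 after quantile normalization and -0.95 before. With the 3' minus 5' control signal as a covariate the difference was -1.09 (SE 0.34). That signal differed little between the groups (actin 0.67 in control and 0.76 in IUGR, *GAPDH* 0.62 and 0.66). The adjustment could thus hardly lower the difference, and it cannot decide on RNA degradation. The signal itself gave no sign, in these transcripts, that degradation moved with the groups. A proportional loss of all non-muscle cells as the whole cause is argued against: minus the mean of the fibroblast, leukocyte and pericyte scores the difference was -0.89 (exact permutation p = 0.0281), and minus that mean with endothelium included it was -0.81 (exact permutation p = 0.0346). A lower rate of cell division, or fewer cells of a dividing type such as myoblasts or endothelium, may account for the pattern, and these stay open hypotheses; control replicate 3, at -1.93, lay among the IUGR arrays.

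The lower endothelial score was weighed in the same way. Array scale is argued against by a difference of -0.37 after quantile normalization. With the 3' minus 5' covariate the difference was -0.38 (SE 0.13), which cannot decide on RNA degradation for the reason given above. A lower share of all non-muscle cells cannot be told apart from a loss of endothelium alone, since the difference from the other marker scores gave an exact permutation p of 0.0887. Fewer vessels, or lower transcription per endothelial cell, may account for it and were not tested.

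The 11 arrays were also split in other ways, with 100 of the 462 splits into 5 and 6 drawn, the real split included. Chance cannot be excluded for the number of lists: 59 of 100 splits gave as many as the real 5, and the highest other gave 13. Such a count points to a structure of the samples, in which the genes of a list vary together between animals. For probe sets past the threshold the real count was 0 and the highest other 2, and for genes 0 and 1, so 100 of 100 splits gave as many for each. At an unadjusted p under 0.05, only the real split, 1 of 100, reached the 1720 probe sets, and the highest other gave 1545. After quantile normalization 3 of 100 splits, the real one included, reached the real 1451, and the highest other gave 1598. Both shares lie under 0.05, which argues against chance for these counts. They do not exclude it, since not all splits were drawn. The first count also holds the difference in array medians between the groups. For the G2/M list itself, 5 of 100 splits, the real one included, gave a camera p as low as the real 5.89e-13. The lowest camera p in another split was 2.08e-19. That share is not under 0.05, so chance cannot be excluded for this list's camera call at the preset correlation.

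The surplus of lower over higher probe sets turned around with scale: the share lower was 34.3% after median centring against 72.3% in the authors' scaling. The share was 49.8% after quantile normalization and 7.4% after hybridization control scaling, so the scaling chosen set the direction of the surplus. Neither bound set for the test by median centring, 45 to 55% or above 65%, was met. That test alone leaves array scale undecided as the source.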
